A study of Homo sapiens with 12 samples.

How the data were processed

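RNA was measured in 12 libraries of THP-1 cells in 4 groups of 3 (vehicle, SK56, LPS and nigericin, LPS and nigericin with SK56), with PMA for 12 h and treatment for 4 h, using a stranded kit on total RNA, per the labels' protocols. The deposited table holds whole-number read counts per Ensembl gene, made by the authors from sequencing reads, with no normalisation that the values show. Per the submitters' processing notes, the build was hg38 and the tools named are HISAT2 2.0.5, StringTie 2.1.5 and Subread, without role or order. The strand setting of the counting, the annotation release and any filter are not given in the sources used here. Genes that overlap or have near-identical copies are therefore called uncertain.

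The table has 62703 genes, of which 58279, with 99.5% of the counts, matched the gene IDs of GENCODE release 29. That release gave biotypes, strands and exon structure, while symbols and coordinates came from the deposited table. Library totals were 13671189 to 17228172 counts. In the MHC region of chromosome 6, 76.2% of the protein-coding genes had a mean under 1 CPM against 40.5% elsewhere, and 2 of 113 other windows of 5 Mb had as high a share, so levels there may be undercounted. Floors for genes at 0 use 3 counts over all libraries and cover counting error only. Replicates were compared before use. Their median chi-square per gene was 1.02 to 1.3 against 0.45 for sampling noise alone, so no pair looked like 1 library deposited more than once.

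Counts were tested with edgeR 4.0.16 (R 4.3.3, limma 3.58.1) after filterByExpr with a minimum count of 10, which kept 16126 genes, and TMM scaling. The quasi-likelihood F test was fitted to all 12 libraries with a term per group, and p-values were adjusted with the Benjamini-Hochberg method and called at 0.05. The 5 contrasts were the SK56 effect in resting cells, the LPS and nigericin effect without SK56, the SK56 effect under LPS and nigericin, the difference between both SK56 effects, and the LPS and nigericin effect with SK56. Every adjusted p of a gene in the text comes from this test unless another is named.

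Gene lists were written before the data were examined, as were the contrasts, the naming rule and the alternatives to be tried. There were 38, of which 33 had at least 5 tested members. They cover inflammasome and pyroptosis machinery, NF-kB inflammatory cytokines, inflammatory chemokines, NF-kB feedback regulators, interferon-stimulated genes, immediate early genes, the unfolded protein, integrated stress and heat shock responses, NRF2 targets, metallothioneins, cholesterol biosynthesis, LXR targets, lysosome and autophagy, glycolysis, hypoxia targets, nuclear and mitochondrial oxidative phosphorylation, cytosolic ribosomal proteins, ribosome biogenesis, cell cycle, histones, p53 targets, the BCL2 family and caspases, membrane repair, MHC class I and II presentation, macrophage and monoblast markers, toll-like receptors, NADPH oxidase and phagocytosis, prostaglandin synthesis, RNA quality, and markers of T, B, mesenchymal, epithelial and erythroid cells. Lists were tested with camera at a preset inter-gene correlation of 0.01 and adjusted over the lists of a contrast, and again with an estimated correlation and with fry. fry asks whether the members of a list move one way on balance and does not compare them with other genes. A list is said to pass or not to pass by camera, unless fry is named.

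Genes were named by a rule. Per contrast it took, among called protein-coding genes with a mean of at least 5 CPM in a group compared and no overlap between the libraries of both groups, the 6 with the largest and the 6 with the smallest log2 fold change. Chance gives such non-overlap in 10% of genes. The interaction used no overlap condition. It took 2 to 4 members with the smallest p of each list that passed or had at least 3 members called, of which part are given as counts, and a panel of 15 pyroptosis and cytokine genes in every contrast. Where lists or scalings are compared, no list median changed sign under DESeq2 size factors or upper-quartile factors.

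Relations between contrasts were measured with Pearson's r across genes. For the pair that shares the LPS and nigericin libraries, 20 series with no effect were simulated. Alternatives were DESeq2 1.42.0 size factors, upper-quartile factors, no low-count filter, a filter at a mean of 5 CPM, the DESeq2 Wald test, the replicate number as a block, each library left out in turn, a threshold of 0.01, only the libraries compared in the fit, and for lists the estimated correlation, fry and adjustment over the list alone. Robust moderation, the table without the MHC region and the table without single-exon coding genes were added after the data were seen. The steps were tested on simulated counts. Of genes made to change 2-fold, 59.7% were recovered for SK56 in resting cells and 38.8% for the interaction (15777 and 15740 genes). Of genes changed 4-fold, 95.5% and 68.2% were recovered. These runs called 136 and 82 genes in all, against 4526 and 2952 in the data. The adjustment was therefore stricter in them, and the shares do not give the sensitivity of the real tests. With an effect given to every gene, a slope of 0.5 between the stimulus effects came back as 0.448 over 15757 genes. It was 0.498 over the 2000 genes of lowest dispersion. The values of 1 gene are not reported here.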

Results

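The transcriptome of human macrophage-like cells was profiled with and without SK56, a peptide, and with and without a stimulus that triggers pyroptosis, the lytic form of cell death driven by inflammasomes and gasdermins. The cells were THP-1, an established line derived from a human monocytic leukaemia, turned into adherent macrophage-like cells by 12 h of phorbol ester (PMA). The stimulus combined 1 µg/ml lipopolysaccharide (LPS), the bacterial ligand of TLR4, with 10 µM nigericin, a potassium ionophore that activates the NLRP3 inflammasome, and SK56 was given at 15 µM. Cells were collected after 4 h. The 12 libraries formed 4 groups of 3, called here vehicle, SK56, LPS and nigericin, and LPS and nigericin with SK56. Their total counts ranged from 13671189 to 17228172, and 16126 of the 62703 genes in the table had enough counts to be tested. Levels are mean counts scaled to the library size, as CPM, ± SD with n = 3. Log2 fold changes carry a standard error (SE), computed as their absolute value divided by the square root of the F statistic.

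The libraries separated by group, with 27.6% of the variance on component 1 and 23.2% on component 2 of a principal component analysis. Mitochondrially encoded genes took 3.81% ± 0.01 of the counts in vehicle, 3.63% ± 0.16 in SK56, 3.69% ± 0.07 in LPS and nigericin, and 2.67% ± 0.04 in LPS and nigericin with SK56. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The unstimulated and the stimulated cells are described as separate sets, so a batch along the stimulus cannot be told apart from the stimulus. Markers of other cell types were read as levels. The highest T cell marker was TRAC at 18.95 CPM, the highest B cell marker CD22 at 3.46 CPM, the highest epithelial marker CLDN7 at 12.7 CPM, the highest erythroid marker HBB at 5.86 CPM and the highest mesenchymal marker COL6A3 at 83.4 CPM, as means over all libraries. The T cell, B cell, epithelial and erythroid lists had 3 tested members each and the MHC class II list had 2, the higher being CTSS at 329.6 CPM, too few for a list test.

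The effect of SK56 in resting cells asked what the peptide does without a challenge. SK56 alone raised immediate early genes, which encode transcription factors and phosphatases that respond rapidly to extracellular signals. EGR1, a zinc finger transcription factor, rose from 158 ± 4.87 CPM in vehicle to 1081 ± 15.7 CPM (log2 fold change 2.77, SE 0.028, adjusted p = 6.05e-13). FOS, a subunit of the AP-1 transcription factor, rose from 49.9 ± 5.97 to 166 ± 22.6 CPM (log2 1.73, SE 0.098, adjusted p = 6.6e-07), and DUSP1, a phosphatase that switches off MAP kinases, from 207 ± 5.98 to 545 ± 20.2 CPM. Of the 22 genes of the list, 13 rose, 2 fell and 7 did not pass (16 and 3 adjusted over the list alone). The list median was 1.07 (camera adjusted p = 4.83e-09, and adjusted p = 0.00352 with an estimated correlation).

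Heat shock genes rose as a list in resting cells. Of 18 members, 10 rose and 0 fell (11 and 0 adjusted over the list alone), with a median of 0.28 (camera adjusted p = 0.000436, and adjusted p = 0.0311 with an estimated correlation). HSPH1, a chaperone of the HSP110 family, rose from 315.5 ± 5.67 to 500.2 ± 21.6 CPM, and HSPA6, a strictly inducible HSP70 whose gene starts 527 bp after FCGR2A on the same strand, from 1.31 ± 0.17 to 3.22 ± 0.06 CPM. Among NF-kB feedback regulators 9 of 19 rose and 2 fell (9 and 3 adjusted over the list alone), with a median of 0.11 (camera adjusted p = 0.0115, but adjusted p = 0.116 with an estimated correlation). SOCS3, an inhibitor of cytokine receptor signalling, rose from 39.0 ± 0.94 to 115.3 ± 0.60 CPM, and TNFAIP3, the ubiquitin-editing enzyme A20, from 203.5 ± 8.24 to 497.7 ± 9.64 CPM. NFKBIA, the inhibitor IkB-alpha, rose from 74.1 ± 3.31 to 191.7 ± 2.07 CPM. TRAF1 fell from 278.5 ± 2.82 to 163.3 ± 1.28 CPM. Cytosolic ribosomal protein genes had a median of 0.17, with 13 of 46 higher and 0 lower by either adjustment (also adjusted over the list alone). Their camera adjusted p of 0.00902 became adjusted p = 0.651 with an estimated correlation.

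Metallothioneins, which bind zinc and copper, went down in resting cells, with 4 of 5 tested members lower and 1 higher (4 and 1 adjusted over the list alone). MT1X fell from 37.9 ± 1.88 to 18.9 ± 0.98 CPM, and MT1E from 12.2 ± 0.62 to 6.00 ± 0.94 CPM. The list median was -0.48 (camera adjusted p = 0.00502, but adjusted p = 0.157 with an estimated correlation), and reads of these near-identical genes may have been split between them. Ribosome biogenesis factors fell in 10 of 24 cases and rose in 1 (11 and 1 adjusted over the list alone), with a median of -0.2 (camera adjusted p = 0.00502, but adjusted p = 0.0546 with an estimated correlation). RRS1, a factor of large subunit assembly, fell from 13.3 ± 1.24 to 4.73 ± 0.45 CPM, whereas the nucleolar chaperone NPM1 rose from 380.2 ± 16.2 to 463.4 ± 8.44 CPM. The median, mean and camera direction differed in sign for the histone, toll-like receptor, monoblast marker, prostaglandin synthesis, cholesterol synthesis and MHC class I lists, none of which passed.

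Genes of pyroptosis did not pass camera as a list in resting cells (camera adjusted p = 0.591). Of 18 members 2 were higher and 4 lower, with a median of -0.09 (2 and 4 adjusted over the list alone). By fry, which does not compare a list with other genes, they were lower on balance (fry adjusted p = 0.0242). NLRP3, the inflammasome sensor (ENSG00000162711, chromosome 1, 247416156 to 247449108, hg38), fell from 68.1 ± 4.14 to 43.1 ± 1.76 CPM (log2 -0.66, SE 0.064, adjusted p = 3.36e-05). IL1B, the main cytokine released through gasdermin pores (ENSG00000125538, chromosome 2, 112829751 to 112836816), stood at 9926 ± 174.3 CPM in vehicle and 9139 ± 335 CPM with SK56 (adjusted p = 0.0266, and 0.053 without SK56 replicate 1). The pore-forming gene GSDMD was at 21.9 ± 4.32 and 17.1 ± 0.39 CPM (adjusted p = 0.0424). That call was lost without vehicle replicate 1 (adjusted p = 0.089), without SK56 replicate 1 (0.069), without SK56 replicate 2 (0.107) and without SK56 replicate 3 (0.0849). With all libraries it was lost for GSDMD with upper-quartile factors (adjusted p = 0.0513), with no low-count filter (0.0598) and with only the groups compared in the fit (0.107). TXNIP, a binding partner of NLRP3, rose from 144.5 ± 2.77 to 271.5 ± 11.4 CPM, the chemokine CXCL8 from 6823 ± 315.6 to 8347 ± 80.6 CPM, and CCL2 fell from 179.8 ± 8.70 to 155.7 ± 8.44 CPM (adjusted p = 0.0166). IL18, CASP1, CASP4, PYCARD, GSDME, NINJ1 and IL6 did not pass, with adjusted p from 0.235 for IL6 to 0.829 for IL18. CASP5 and IL10 had 9 and 63 counts over all libraries and were not tested. IL6 overlaps STEAP1B, IL10 overlaps IL19 and IL18 overlaps a gene without a symbol, so the reads of these genes are uncertain in every comparison. TNF had 0 counts in every library, which by counting error alone allows up to 0.0162 CPM over the series. It lies in the MHC region of chromosome 6, where 78 of 181 protein-coding genes had 0 counts. Its level may therefore be undercounted, and the limit would not cover that.

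Of the protein-coding genes with the steepest rise in resting cells, FAM83C went from 0.11 ± 0.05 to 5.22 ± 0.24 CPM (log2 5.42, SE 0.432, adjusted p = 8.46e-06). The growth factor gene FGF18 (ENSG00000156427, chromosome 5, 171419647 to 171457626) rose from 0.23 ± 0.06 to 8.01 ± 1.13 CPM. The muscle glycogen phosphorylase gene PYGM (ENSG00000068976, chromosome 11, 64746389 to 64759974) rose from 0.30 ± 0.19 to 8.37 ± 1.71 CPM. HSPA2 rose from 0.63 ± 0.22 to 13.35 ± 1.305 CPM, and CSPG5 from 0.42 ± 0.15 to 8.41 ± 1.65 CPM. FGF18 starts 7837 bp after the end of NPM1 on the same strand, PYGM 4632 bp after SF1, HSPA2 2215 bp after ZBTB1, CSPG5 4477 bp after SMARCC1 and FAM83C 10141 bp after UQCC1. TSC22D3, the glucocorticoid-inducible GILZ gene (ENSG00000157514, chromosome X, 107713221 to 107777342), rose from 3.71 ± 0.84 to 59.6 ± 12.9 CPM (log2 4.01, SE 0.185, adjusted p = 1.65e-07), with the nearest expressed upstream gene 306865 bp away. PHACTR2, a regulator of phosphatase 1 and actin, fell from 51.3 ± 1.41 to 3.14 ± 0.22 CPM (log2 -4.03, SE 0.632, adjusted p = 0.00083). Its level was unstable within the LPS and nigericin group, at 26.2, 2.62 and 25.0 CPM in replicates 1, 2 and 3. The mitochondrial fission factor MIEF2 fell from 7.63 ± 1.36 to 0.97 ± 0.60 CPM. CCDC71 fell from 12.0 ± 0.36 to 2.18 ± 0.40 CPM. PLPP6 and MOCS3 also fell but overlap SPATA6L and DPM1, so their reads are uncertain. ZNF324B stood at 6.24 ± 1.80 and 1.68 ± 0.97 CPM (adjusted p = 0.0164), a call lost without vehicle replicate 1 (adjusted p = 0.0541), SK56 replicate 2 (0.0625) or SK56 replicate 3 (0.0629). In all, 2376 genes were higher and 2150 lower with SK56, of which 604 and 344 by more than 2-fold. At a mean of at least 5 CPM the lower genes were the more numerous, with 1802 higher and 2036 lower.

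A grouping chosen after these values were seen set low-expressed protein-coding genes (mean under 5 CPM) by their distance from the nearest expressed gene upstream on their strand. In resting cells the 215 genes within 5 kb had a median log2 fold change of 0.4 with SK56, with 63 higher and 9 lower. The 1511 genes over 200 kb away had a median of -0.06, with 88 higher and 156 lower. Under the stimulus the medians were 0.3 and 0.02.

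**Figure D1:**
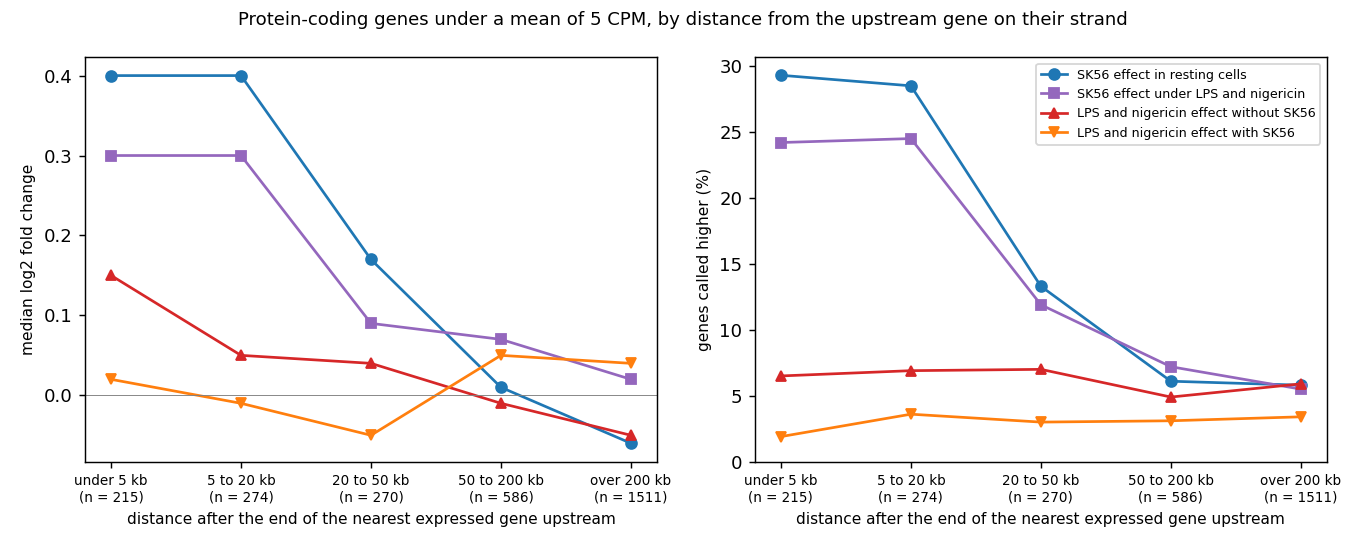
Median log2 fold change (left) and percentage of genes called higher (right) of low-expressed protein-coding genes in bins of distance after the nearest expressed gene upstream on their strand, for both SK56 effects and both stimulus effects. For SK56 in resting cells the median was 0.4 under 5 kb and -0.06 over 200 kb, and 29.3% and 5.8% of genes were called higher.

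The effect of LPS and nigericin without SK56 asked what the pyroptosis stimulus does. The stimulus raised the histone, heat shock, metallothionein and immediate early lists, with median log2 fold changes of 3.23, 1.11, 2.73 and 2.06. H2BC12, a core histone gene, rose from 27.6 ± 2.17 to 258.5 ± 8.19 CPM (log2 3.23, SE 0.069, adjusted p = 6.77e-11). HSPA6 rose from 1.31 ± 0.17 to 27.2 ± 0.70 CPM (log2 4.37, SE 0.078, adjusted p = 1.95e-11). MT1X rose from 37.9 ± 1.88 to 347.4 ± 10.9 CPM (log2 3.2, SE 0.054, adjusted p = 1.11e-11), and EGR1 from 158 ± 4.87 to 2732 ± 18.0 CPM (log2 4.11, SE 0.030, adjusted p = 1.68e-14). TNFSF9, the ligand of the costimulatory receptor 4-1BB, stood at 113.7 ± 5.28 CPM in vehicle and 1005 ± 19.2 CPM under the stimulus. IL1B, at 9926 ± 174.3 and 9270 ± 281.3 CPM, lay close to the threshold on either side (adjusted p = 0.0551). It passed with DESeq2 size factors (adjusted p = 0.0435), at a mean of at least 5 CPM (0.0167), with robust moderation (0.0486), without MHC genes (0.0357) and without LPS and nigericin replicate 2 (0.0279).

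All 10 tested replication-dependent histone genes rose, with a median of 3.23 (10 adjusted over the list alone, camera adjusted p = 5.39e-25, and adjusted p = 6.49e-05 with an estimated correlation). H2BC21 rose from 18.9 ± 1.19 to 178.1 ± 2.57 CPM, and H2BC7, H2BC6, H2BU1 and H2BC8 were among the genes with the steepest rise, though histone genes are close copies and their reads may be shared. Of 18 heat shock genes 16 rose and 0 fell (16 and 0 adjusted over the list alone, median 1.11, camera adjusted p = 3.18e-22). BAG3, a co-chaperone of HSP70, rose from 132.6 ± 5.21 to 424.1 ± 8.31 CPM. Of 22 immediate early genes 18 rose and 0 fell (18 and 0 adjusted over the list alone, median 2.06, camera adjusted p = 4.18e-27). JUN, another AP-1 subunit, rose from 404.8 ± 23.6 to 2019 ± 57.1 CPM and DUSP1 from 207 ± 5.98 to 2157 ± 25.0 CPM. Metallothioneins rose in 4 of 5 cases (4 adjusted over the list alone, median 2.73, camera adjusted p = 1.21e-08), with MT2A from 77.3 ± 1.86 to 512.8 ± 33.8 CPM.

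Stress and sterol pathways also rose under the stimulus. Of 20 unfolded protein response genes 10 rose and 0 fell (13 and 0 adjusted over the list alone, median 0.29, camera adjusted p = 0.00014), including HSPA5, the chaperone BiP, from 783.8 ± 16.5 to 1091 ± 19.4 CPM. Of 21 integrated stress response genes 12 rose and 1 fell (14 and 2 adjusted over the list alone, median 0.37, camera adjusted p = 0.000566). DDIT3, the transcription factor CHOP, rose from 58.7 ± 1.73 to 184.5 ± 25.1 CPM, although this gene overlaps MARS1 and MBD6 and its reads are uncertain. Cholesterol synthesis genes rose in 9 of 23 cases and fell in 1 (9 and 1 adjusted over the list alone, median 0.25, camera adjusted p = 0.000413). INSIG1, a brake on sterol synthesis, rose from 490.3 ± 7.56 to 1753 ± 67.4 CPM. Targets of the sterol receptor LXR rose in 6 of 11 cases and fell in 0 (8 and 1 adjusted over the list alone, median 0.31, camera adjusted p = 0.00014). MYLIP, which degrades the LDL receptor, rose from 23.5 ± 1.10 to 110.5 ± 2.60 CPM. Glycolysis genes rose in 10 of 20 cases and fell in 1 (10 and 1 adjusted over the list alone, median 0.22, camera adjusted p = 0.00503). Hypoxia targets rose in 7 of 19 with 2 lower (8 and 2 adjusted over the list alone, median 0.29, camera adjusted p = 0.00784). Cytosolic ribosomal proteins rose in 33 of 46 with 0 lower (39 and 0 adjusted over the list alone, median 0.39, camera adjusted p = 1.3e-12). The RNA quality list rose in 5 of 12 cases and fell in 0 (6 and 1 adjusted over the list alone, median 0.2, camera adjusted p = 0.00692). Its leading members were the snoRNA host genes SNHG1 and GAS5, of which GAS5 overlaps ZBTB37. Ribosome biogenesis factors fell, with 11 of 24 lower and 4 higher (13 and 4 adjusted over the list alone, median -0.23, camera adjusted p = 0.00732), among them WDR43 from 61.5 ± 0.71 to 28.9 ± 1.04 CPM. These 13 list calls held with an estimated correlation, with adjusted p from 6.12e-05 for immediate early genes to 0.0452 for cholesterol synthesis and for hypoxia targets.

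Further list calls under the stimulus were lost with an estimated correlation. Chemokines rose in 7 of 14 cases and fell in 3 (7 and 3 adjusted over the list alone, camera adjusted p = 0.0167, but adjusted p = 0.213 with an estimated correlation), including CXCL2 from 103.1 ± 8.49 to 278.4 ± 15.2 CPM and CCL3, which has near-identical copies. Nuclear-encoded oxidative phosphorylation genes rose in 13 of 33 cases and fell in 0 (16 and 0 adjusted over the list alone, camera adjusted p = 0.000566, but adjusted p = 0.176 with an estimated correlation). Mitochondrially encoded mRNAs rose in 8 of 13 cases and fell in 1 (9 and 1 adjusted over the list alone, camera adjusted p = 0.0054, but adjusted p = 0.382 with an estimated correlation). MT-ND2, a complex I subunit, rose from 1209 ± 10.1 to 2304 ± 50.2 CPM while MT-ND6, the complex I subunit encoded on the opposite strand, fell from 314.5 ± 24.9 to 116.4 ± 10.0 CPM. Targets of p53 rose in 7 of 19 cases and fell in 3 (7 and 4 adjusted over the list alone, camera adjusted p = 0.0179, but adjusted p = 0.054 with an estimated correlation), with GADD45A from 19.2 ± 2.20 to 122.3 ± 7.03 CPM. MHC class I presentation genes rose in 4 of 12 cases and fell in 0 (4 and 0 adjusted over the list alone, camera adjusted p = 0.0367, but adjusted p = 0.085 with an estimated correlation). Toll-like receptors and adaptors fell in 6 of 14 cases and rose in 1 (7 and 1 adjusted over the list alone, camera adjusted p = 0.00784, but adjusted p = 0.0773 with an estimated correlation), with TICAM1, the adaptor TRIF, from 47.1 ± 1.26 to 25.6 ± 0.45 CPM.

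The pyroptosis list did not pass camera under the stimulus (camera adjusted p = 0.717). Of 18 members 3 were higher and 1 lower, with a median of 0.02 (3 and 1 adjusted over the list alone). By fry the list was higher on balance (fry adjusted p = 0.00683). NLRP3 rose from 68.1 ± 4.14 to 83.6 ± 5.51 CPM (log2 0.29, SE 0.063, adjusted p = 0.00435) and CXCL8 from 6823 ± 315.6 to 8334 ± 158 CPM, while CCL2 fell from 179.8 ± 8.70 to 132.8 ± 6.60 CPM (adjusted p = 0.000142). IL6, whose reads are uncertain because it overlaps STEAP1B, was near the limit of detection, at 0.42 ± 0.11 CPM under the stimulus (log2 -1.36, SE 0.409, adjusted p = 0.0271). The IL6 call was lost without vehicle replicate 2 (adjusted p = 0.0618), vehicle replicate 3 (0.0937), LPS and nigericin replicate 2 (0.0936) or LPS and nigericin replicate 3 (0.0732). IL18, CASP1, CASP4, PYCARD, GSDMD, GSDME and NINJ1 did not pass, with adjusted p from 0.16 for CASP4 to 0.862 for GSDME. DLX3, a homeobox gene, fell from 18.0 ± 0.36 to 2.15 ± 0.61 CPM and the potassium channel gene KCNJ2 from 12.3 ± 1.58 to 2.37 ± 0.50 CPM. HSPA1B had the steepest rise, from 0.08 ± 0.07 to 10.53 ± 0.31 CPM, but is nearly identical to HSPA1A and its reads are uncertain. In all, 2338 genes were higher and 2530 lower, of which 458 and 414 by more than 2-fold. The median and mean differed in sign for the membrane repair list, which did not pass.

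**Figure D2:**
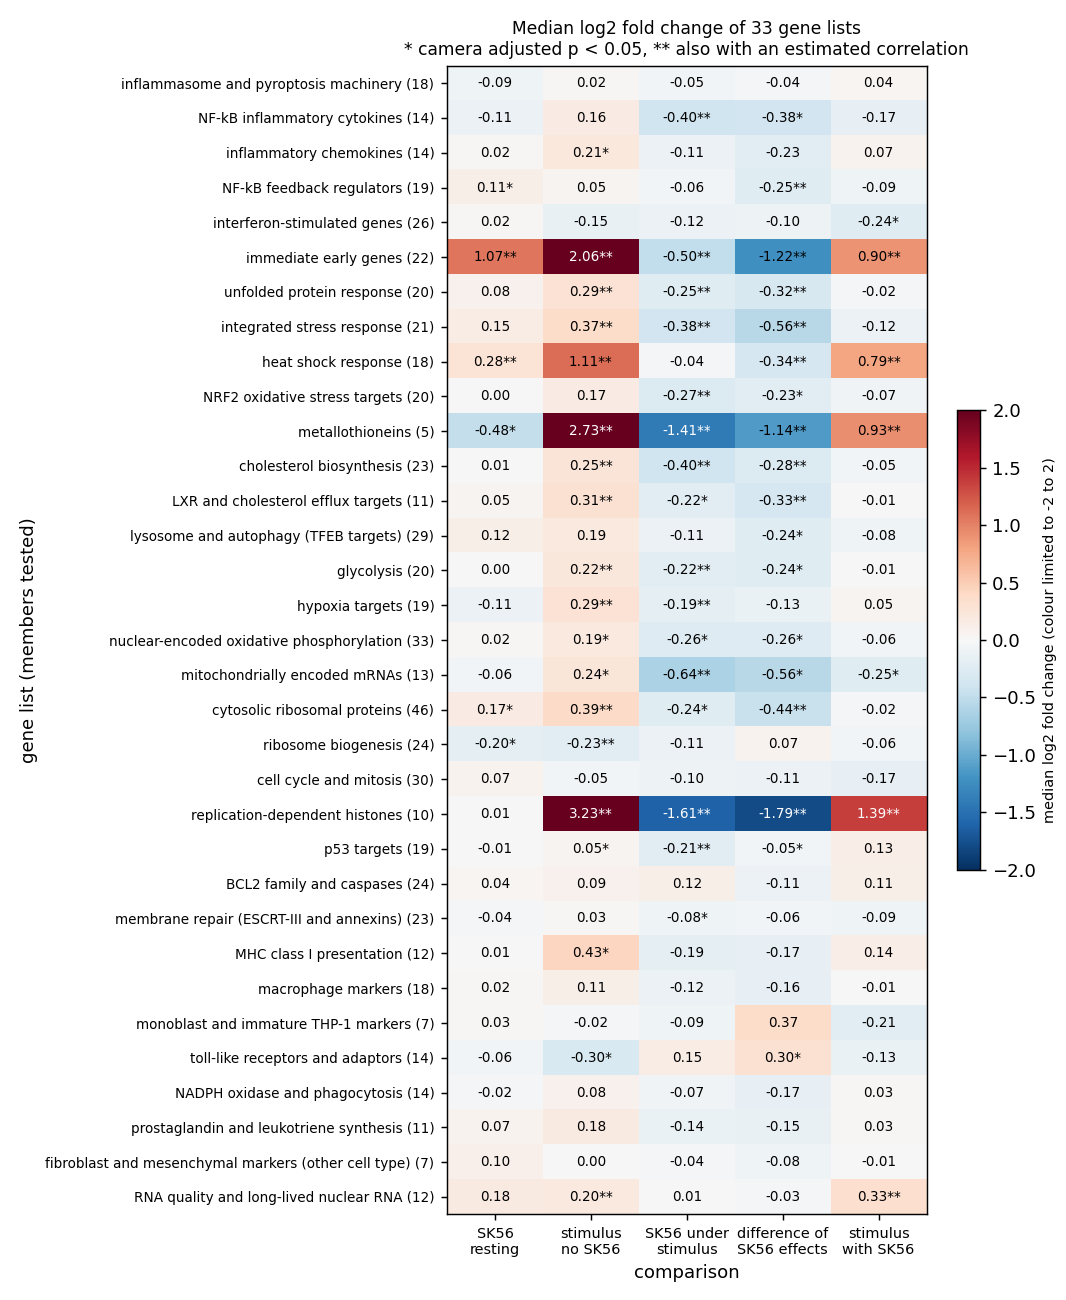
Median log2 fold change of each of 33 gene lists (vertical axis, with the number of members tested) in 5 comparisons (horizontal axis), where colour and printed value both give the median. Single asterisks mark a camera adjusted p under 0.05 and double asterisks a call that also held with an estimated correlation, as for histones at 3.23 without SK56 and -1.61 for SK56 under the stimulus.

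The effect of SK56 under LPS and nigericin addressed the question in the title of the series, which genes the peptide targets during pyroptosis. In stimulated cells SK56 lowered inflammatory cytokine genes, metallothioneins, histones, sterol synthesis genes and mitochondrial mRNAs, and no list passed camera as higher. TNFSF9 fell from 1005 ± 19.2 to 151.7 ± 5.27 CPM (log2 -2.73, SE 0.046, adjusted p = 7e-11). NLRP3 fell from 83.6 ± 5.51 to 43.1 ± 1.37 CPM (log2 -0.95, SE 0.064, adjusted p = 1.78e-06). IL1B fell from 9270 ± 281.3 to 7254 ± 270.2 CPM (log2 -0.35, SE 0.035, adjusted p = 3.22e-05), as did CXCL8, from 8334 ± 158 to 5918 ± 293.6 CPM (log2 -0.49, SE 0.039, adjusted p = 6.84e-06). GSDMD fell from 21.1 ± 1.38 to 14.7 ± 0.20 CPM (log2 -0.52, SE 0.119, adjusted p = 0.00729). HSPA6 went the other way, from 27.2 ± 0.70 to 175.1 ± 7.12 CPM (log2 2.69, SE 0.061, adjusted p = 5.81e-10).

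Of 14 NF-kB inflammatory cytokines 7 fell and 0 rose (7 and 0 adjusted over the list alone, median -0.4, camera adjusted p = 8.97e-06). LIF fell from 4828 ± 34.9 to 3089 ± 40.9 CPM, TNFSF15 from 5178 ± 125.1 to 3643 ± 62.7 CPM, OSM, a cytokine of the IL-6 family, from 38.3 ± 1.66 to 12.9 ± 0.81 CPM, and IL23A from 282.6 ± 8.38 to 191.2 ± 7.24 CPM. All 5 metallothioneins fell (5 adjusted over the list alone, median -1.41, camera adjusted p = 1.52e-11), with MT1X from 347.4 ± 10.9 to 69.7 ± 1.06 CPM. Of 10 histone genes 9 fell and 0 rose (9 and 0 adjusted over the list alone, median -1.61, camera adjusted p = 1.33e-13), with H2BC12 from 258.5 ± 8.19 to 64.1 ± 2.67 CPM and H2BC4 from 54.3 ± 3.29 to 5.47 ± 0.20 CPM. Of 22 immediate early genes 9 fell and 3 rose (11 and 3 adjusted over the list alone, median -0.5, camera adjusted p = 0.000187). BTG2, an antiproliferative p53 target, fell from 1582 ± 26.7 to 518.3 ± 18.9 CPM and DUSP1 from 2157 ± 25.0 to 1227 ± 23.1 CPM. These calls held with an estimated correlation, with adjusted p from 0.0013 for histones to 0.0217 for cytokines.

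Stress and sterol lists fell in the same comparison. Of 20 unfolded protein response genes 9 fell and 1 rose (11 and 2 adjusted over the list alone, median -0.25, camera adjusted p = 0.000318), with XBP1, a transcription factor of that response, from 162.5 ± 29.02 to 73.9 ± 4.72 CPM. Of 21 integrated stress response genes 11 fell and 1 rose (13 and 1 adjusted over the list alone, median -0.38, camera adjusted p = 0.000114), including the amino acid transporter SLC7A5 from 343.9 ± 2.49 to 239.9 ± 2.05 CPM. Of 20 NRF2 targets 9 fell and 1 rose (15 and 1 adjusted over the list alone, median -0.27, camera adjusted p = 0.000187), with the haem-degrading enzyme HMOX1 from 223.4 ± 4.15 to 133.5 ± 2.44 CPM. Of 23 cholesterol synthesis genes 14 fell and 0 rose (16 and 0 adjusted over the list alone, median -0.4, camera adjusted p = 1.23e-07). INSIG1 fell from 1753 ± 67.4 to 538.9 ± 4.84 CPM. Glycolysis genes fell in 11 of 20 cases (11 adjusted over the list alone, median -0.22, camera adjusted p = 0.00131). Hypoxia targets fell in 6 of 19 (6 adjusted over the list alone, median -0.19, camera adjusted p = 0.00863) and p53 targets in 7 of 19 with 1 higher (7 and 1 adjusted over the list alone, median -0.21, camera adjusted p = 0.00131). Mitochondrially encoded mRNAs fell in 12 of 13 cases (12 adjusted over the list alone, median -0.64, camera adjusted p = 1.01e-17), with MT-CO1 from 9409 ± 229.7 to 5562 ± 40.6 CPM, in the group whose mitochondrial share of counts was 2.67%. Each of these calls held with an estimated correlation, the weakest being hypoxia targets at 0.0481.

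The calls of 4 lower lists were lost. LXR targets fell in 7 of 11 cases and rose in 1 (7 and 1 adjusted over the list alone, camera adjusted p = 0.0185, but adjusted p = 0.103 with an estimated correlation), with MYLIP rising from 110.5 ± 2.60 to 152.5 ± 3.96 CPM. Nuclear-encoded oxidative phosphorylation genes fell in 14 of 33 cases (19 adjusted over the list alone, camera adjusted p = 1.41e-05, but adjusted p = 0.108 with an estimated correlation). Cytosolic ribosomal proteins fell in 25 of 46 cases (30 adjusted over the list alone, camera adjusted p = 1.21e-07, but adjusted p = 0.0774 with an estimated correlation). Membrane repair genes, which seal plasma membrane wounds, fell in 8 of 23 cases and rose in 1 (8 and 1 adjusted over the list alone, camera adjusted p = 0.0246, but adjusted p = 0.218 with an estimated correlation). The ESCRT-III subunit gene CHMP1B fell from 165.6 ± 8.80 to 102.3 ± 3.99 CPM.

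Genes of pyroptosis and of LPS sensing did not pass camera as lists under SK56 in stimulated cells. By fry, which does not compare a list with other genes, both passed. The pyroptosis list was lower on balance (fry adjusted p = 9.48e-05) and the toll-like receptor list higher (fry adjusted p = 0.000412). In the pyroptosis list 3 of 18 genes rose and 4 fell (3 and 4 adjusted over the list alone, median -0.05, camera adjusted p = 0.173). PANX1, a channel gene, fell from 52.2 ± 4.12 to 40.6 ± 2.37 CPM (adjusted p = 0.00345). CASP4, the sensor of cytosolic LPS, stood at 27.3 ± 2.77 and 32.8 ± 2.08 CPM (adjusted p = 0.025), a call lost without LPS and nigericin replicate 3 (adjusted p = 0.0699) and without LPS and nigericin with SK56 replicate 1 (0.0818) or replicate 2 (0.0685). The CASP4 call was also lost with no low-count filter (adjusted p = 0.0658) and with only the groups compared in the fit (0.0705). NINJ1, which ruptures the plasma membrane in lytic death, stood at 55.4 ± 11.1 and 44.1 ± 8.95 CPM (adjusted p = 0.163, and 0.0413 without LPS and nigericin with SK56 replicate 2). IL18, CASP1, PYCARD, GSDME and IL6 did not pass, with adjusted p from 0.16 for IL6 to 0.969 for IL18. Toll-like receptors and adaptors had 4 of 14 genes higher and 1 lower (4 and 2 adjusted over the list alone, camera adjusted p = 0.0965). Within that list TICAM1 rose from 25.6 ± 0.45 to 63.5 ± 2.29 CPM, and the LPS co-receptor gene CD14 from 1.84 ± 0.67 to 5.82 ± 1.082 CPM. CCL2 rose from 132.8 ± 6.60 to 165.4 ± 4.50 CPM, and TNFAIP3 from 183.0 ± 6.25 to 388.2 ± 6.75 CPM, while ICAM1 fell from 2043 ± 62.2 to 1376 ± 38.2 CPM.

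Lists that passed camera in no comparison included those of cell identity and of cell growth. For SK56 under the stimulus, 8 of 18 macrophage markers fell and 1 rose (camera adjusted p = 0.161), 6 of 14 NADPH oxidase and phagocytosis genes fell and 1 rose (0.243), and 3 of 11 prostaglandin and leukotriene synthesis genes fell and 1 rose (0.27). Of 30 cell cycle genes 6 fell and 5 rose (0.653), and 5 of 24 BCL2 family and caspase genes fell and 6 rose (0.573). Of 7 monoblast markers 0 fell and 1 rose (0.996), and of 7 mesenchymal markers 0 fell and 1 rose (0.996). Adjusted over the list alone these counts were 8 and 1, 6 and 1, 3 and 1, 7 and 6, 5 and 6, 0 and 0, and 0 and 1. By fry the macrophage, NADPH oxidase and prostaglandin lists were lower on balance here (fry adjusted p = 0.00139, 0.00209 and 0.0258). The cell cycle, BCL2 family, monoblast and mesenchymal lists did not pass fry in this comparison. The median, mean and camera direction differed in sign for the heat shock, NF-kB feedback, macrophage, RNA quality, mesenchymal and monoblast lists, none of which passed camera in this comparison.

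The steepest rises with SK56 in stimulated cells again included genes close behind an expressed gene. SSTR3 (ENSG00000278195, chromosome 22, 37204237 to 37212477), 12793 bp after RAC2, rose from 0.26 ± 0.14 to 10.8 ± 0.99 CPM (log2 5.37, SE 0.277, adjusted p = 2.26e-07). FGF18 rose from 0.55 ± 0.14 to 15.2 ± 0.76 CPM, and IQCN (ENSG00000130518, chromosome 19, 18257098 to 18274500) from 6.85 ± 0.04 to 88.97 ± 10.96 CPM (log2 3.7, SE 0.111, adjusted p = 3.85e-09). IQCN starts 5194 bp after JUND, which itself fell by 1.01 on the log2 scale. BIVM-ERCC5 had the largest fitted rise but overlaps ERCC5 and BIVM, and its reads are uncertain. Besides H2BC4 and TNFSF9, the steepest falls included that of PROK2, a secreted chemoattractant, from 7.25 ± 0.72 to 0.85 ± 0.28 CPM. Among them were also BOLA1, from 6.70 ± 0.82 to 1.03 ± 0.23 CPM, and HES4, from 7.11 ± 0.98 to 1.24 ± 0.10 CPM. In all, 2421 genes were higher and 2213 lower, of which 540 and 272 by more than 2-fold.

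**Figure D3:**
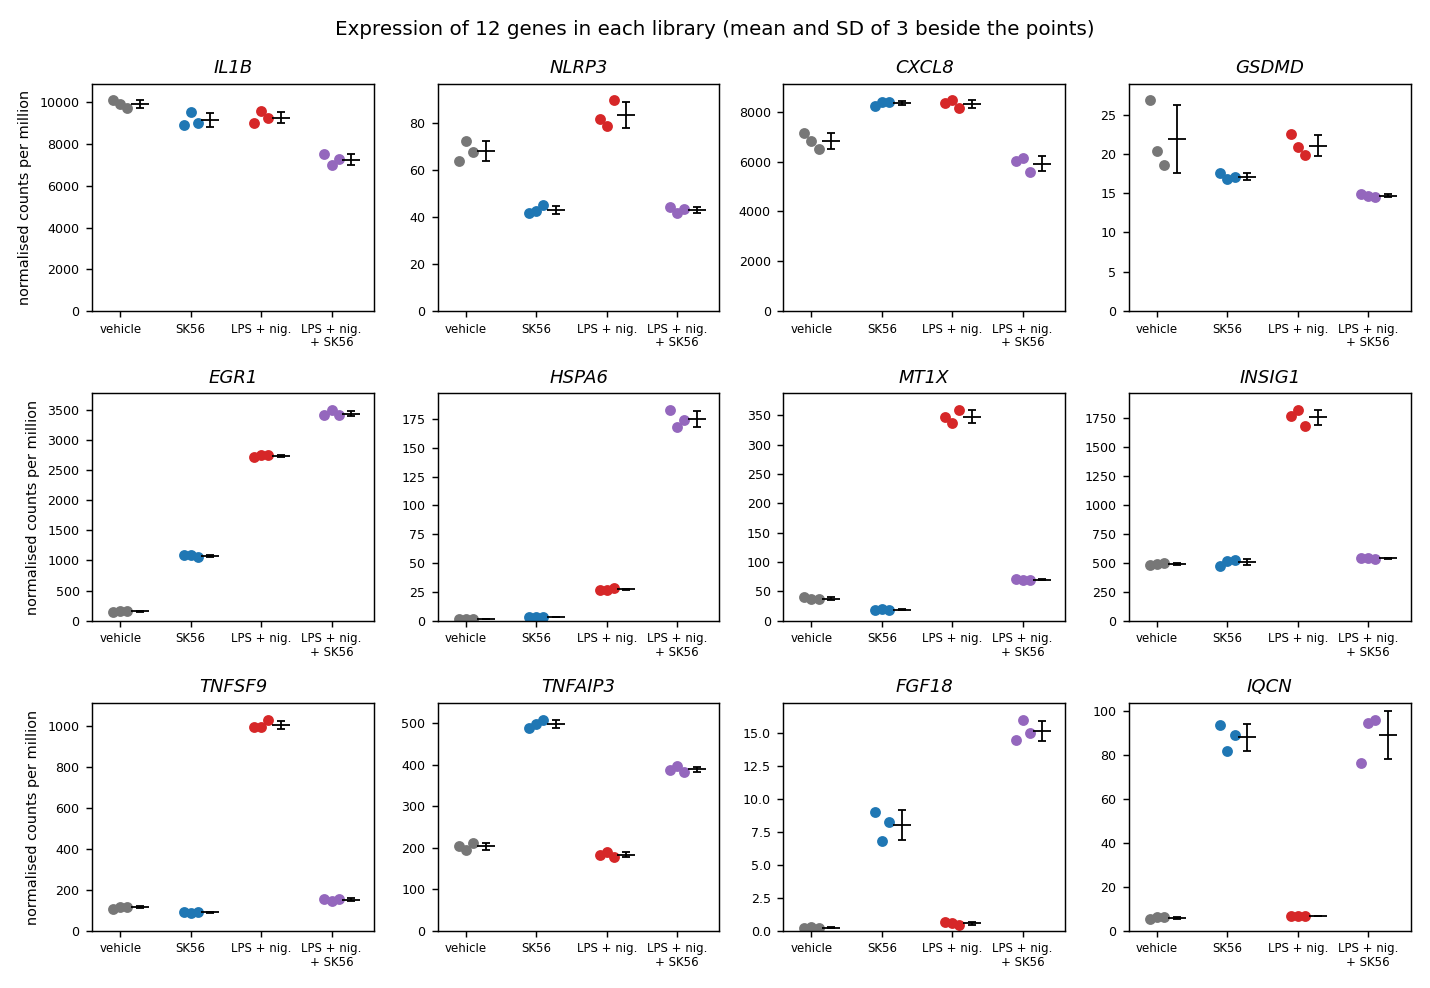
Normalised CPM of 12 genes in each of the 3 libraries of 4 groups (points), with the mean and SD beside them. NLRP3 lay at 43.1 CPM in both groups given SK56, against 68.1 in vehicle and 83.6 under LPS and nigericin, and INSIG1, MT1X and TNFSF9 were highest under LPS and nigericin without SK56.

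The interaction asked whether SK56 acted differently in stimulated and in resting cells. It did for 2952 genes, with 1406 having a higher and 1546 a lower SK56 effect under the stimulus. At a mean of at least 5 CPM the balance turned, with 1681 higher and 1381 lower. TSC22D3, at 3.71 ± 0.84 CPM in vehicle and 59.6 ± 12.9 with SK56, went only from 71.8 ± 2.68 to 85.5 ± 3.70 CPM in stimulated cells (log2 difference -3.75, SE 0.237, adjusted p = 2.14e-06). EGR1 and DUSP1 had lower SK56 effects under the stimulus (log2 differences -2.44, SE 0.038, and -2.21, SE 0.048), as did MT-CO1 (-0.8, SE 0.031, adjusted p = 3.49e-08) and CXCL8 (-0.79, SE 0.056, adjusted p = 5.04e-06). HSPA6 had a higher one (1.4, SE 0.111, adjusted p = 1.26e-05). For IL1B the difference was -0.23 (SE 0.050, adjusted p = 0.00747). NLRP3 fell with SK56 both at rest and under the stimulus, and its difference of -0.3 (adjusted p = 0.0425) was lost when any of 10 libraries was left out. The adjusted p was 0.121 without vehicle replicate 1, 0.0975 without vehicle replicate 3, and 0.065, 0.0649 and 0.106 without SK56 replicates 1, 2 and 3. It was 0.061 and 0.109 without LPS and nigericin replicates 1 and 3, and 0.0671, 0.111 and 0.0734 without LPS and nigericin with SK56 replicates 1, 2 and 3. With all libraries the NLRP3 call was lost with DESeq2 size factors (adjusted p = 0.0523), no low-count filter (0.112), a mean of at least 5 CPM (0.0523), the replicate block (0.057), the DESeq2 Wald test (0.053) and without MHC genes (0.0525).

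By list, the SK56 effect was lower under the stimulus for immediate early genes (median difference -1.22, 13 of 22 lower and 0 higher, camera adjusted p = 2.98e-20), histones (-1.79, 8 of 10 and 0, 7.16e-12), and metallothioneins (-1.14, 4 of 5 and 0, 4.21e-06). It was also lower for the integrated stress response (-0.56, 10 of 21 and 1, 1.45e-05), ribosomal proteins (-0.44, 27 of 46 and 0, 2.4e-12) and heat shock genes (-0.34, 9 of 18 and 1, 0.000437). The same held for LXR targets (-0.33, 6 of 11 and 0, 0.000677), the unfolded protein response (-0.32, 9 of 20 and 0, 1.45e-05), cholesterol synthesis (-0.28, 8 of 23 and 1, 1.84e-05) and NF-kB feedback regulators (-0.25, 8 of 19 and 2, 0.00416). Adjusted over the list alone the lower and higher counts were, in that order, 14 and 0, 8 and 0, 4 and 0, 15 and 1, 34 and 0, 9 and 1, 6 and 0, 12 and 0, 10 and 1, and 9 and 3. These 10 calls held with an estimated correlation, the weakest being NF-kB feedback regulators at 0.041. A further 8 were lost. NF-kB inflammatory cytokines had 7 of 14 genes lower and 0 higher (7 and 1 adjusted over the list alone, camera adjusted p = 0.000437, but adjusted p = 0.0639 with an estimated correlation). Mitochondrially encoded mRNAs had 11 of 13 and 0 (12 and 0 adjusted over the list alone, 7.16e-12, but adjusted p = 0.0778 with an estimated correlation). Nuclear-encoded oxidative phosphorylation had 10 of 33 and 0 (13 and 0 adjusted over the list alone, 2.45e-05, but adjusted p = 0.104 with an estimated correlation). NRF2 targets had 6 of 20 lower and 1 higher (9 and 3 adjusted over the list alone, 0.0292, but adjusted p = 0.0829 with an estimated correlation). Lysosome and autophagy genes had 8 of 29 and 2 (8 and 2 adjusted over the list alone, 0.0135, but adjusted p = 0.0891 with an estimated correlation). Glycolysis had 5 of 20 and 1 (5 and 1 adjusted over the list alone, 0.0356, but adjusted p = 0.0778 with an estimated correlation), as had p53 targets, with 5 of 19 and 2 (6 and 2 adjusted over the list alone, 0.0356, but adjusted p = 0.0778 with an estimated correlation). Toll-like receptors and adaptors were the only list that passed with a higher SK56 effect, with 3 of 14 higher and 1 lower (5 and 1 adjusted over the list alone, 0.0457, but adjusted p = 0.152 with an estimated correlation). The median and mean differed in sign for the RNA quality list, which did not pass.

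Across the 16126 genes, which are not independent replicates, the stimulus effect and the SK56 effect under the stimulus were inversely related (Pearson r = -0.324). These comparisons share the LPS and nigericin libraries, and 20 simulated series with no effect gave r = -0.52 on average, and a covariance of -0.063 against -0.156 observed, a difference of -0.0934. Signs were opposite for 65.5% of genes, against 67% in the simulations. Of 2338 genes raised by the stimulus, 1121 (47.9%) fell with SK56 under it, against 320.8 for independent lists, and of 2530 genes lowered by the stimulus, 980 rose, against 379.8. The simulated series gave at most 1 such opposite call, but they hold no effect and so almost no calls, while the values for independent lists leave out the shared libraries. Neither is the overlap to be had from unrelated effects measured against the same libraries. The 3 shared libraries cannot be split into parts of at least 2, so part of the excess may come from them.

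The other pairs of comparisons share no library. The stimulus effects without and with SK56 had r = 0.37 and a slope of 0.289 across genes. Both raised 429 genes, against 135.4 for independent lists, and lowered 512, against 162.9. Both stimulus effects compare unstimulated with stimulated cells, so a batch along that line would enter both. It could add to r and to these overlaps. The SK56 effects in resting and in stimulated cells had r = 0.461 and a slope of 0.452, and shared 1038 higher genes, against 356.7, and 670 lower genes, against 295. With no low-count filter r was 0.092 for the stimulus effects and 0.204 for the SK56 effects. Noise in the effect on the horizontal axis lowers such slopes, and in simulated counts a slope made as 0.5 for the stimulus effects came out as 0.448. That simulation gave every gene a stimulus effect, so it does not give the size of the lowering in these data.

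**Figure D4:**
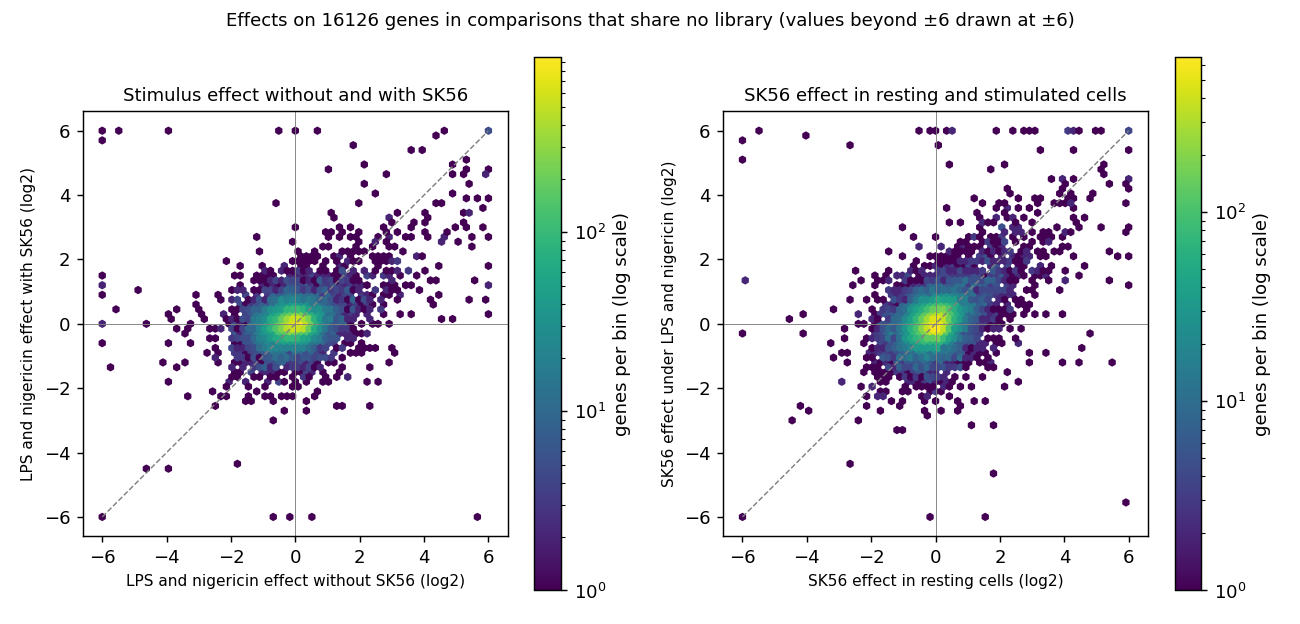
Log2 fold changes of 16126 genes, as the number of genes per hexagonal bin on a log colour scale, for the stimulus effect without SK56 (horizontal) against that with SK56 (vertical) on the left, and for SK56 in resting (horizontal) against stimulated cells (vertical) on the right. The dashed line marks equal effects, and the slopes were 0.289 and 0.452.

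The effect of LPS and nigericin with SK56 asked what remained of the stimulus response in treated cells. The heat shock, immediate early, histone and metallothionein lists still rose. HSPA6 rose from 3.22 ± 0.06 CPM with SK56 alone to 175.1 ± 7.12 CPM (log2 5.76, SE 0.074, adjusted p = 6.91e-12). FOS rose from 166 ± 22.6 to 1243 ± 25.2 CPM (log2 2.9, SE 0.1, adjusted p = 1.23e-08) and MT1X from 18.9 ± 0.98 to 69.7 ± 1.06 CPM (log2 1.88, SE 0.053, adjusted p = 2.4e-09). Of 18 heat shock genes 14 rose and 1 fell (15 and 1 adjusted over the list alone, median 0.79, camera adjusted p = 9.52e-26). Of 22 immediate early genes 13 rose and 2 fell (13 and 4 adjusted over the list alone, median 0.9, camera adjusted p = 3.13e-16). Of 10 histone genes 7 rose and 0 fell (8 and 0 adjusted over the list alone, median 1.39, camera adjusted p = 2.06e-21). Of 5 metallothioneins 3 rose and 0 fell (3 and 0 adjusted over the list alone, median 0.93, camera adjusted p = 6.01e-08). The RNA quality list rose alongside, with 4 of 12 higher and 0 lower (5 and 0 adjusted over the list alone, median 0.33, camera adjusted p = 0.000929). These 5 calls held with an estimated correlation, with adjusted p from 0.000108 for heat shock genes to 0.0274 for the RNA quality list.

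Mitochondrially encoded mRNAs and interferon-stimulated genes were the lists that passed as lower in treated cells under the stimulus, and neither call held with an estimated correlation. Mitochondrially encoded mRNAs fell in 8 of 13 cases and rose in 1 (9 and 1 adjusted over the list alone, median -0.25, camera adjusted p = 2.86e-07, but adjusted p = 0.286 with an estimated correlation), with MT-CO1 from 9910 ± 189.1 to 5562 ± 40.6 CPM. Interferon-stimulated genes fell in 4 of 26 cases and rose in 0 (4 and 0 adjusted over the list alone, median -0.24, camera adjusted p = 0.00285, but adjusted p = 0.203 with an estimated correlation). IFIH1, the RNA sensor MDA5, fell from 31.3 ± 1.33 to 23.9 ± 0.78 CPM. IL1B fell from 9139 ± 335 to 7254 ± 270.2 CPM (log2 -0.33, SE 0.035, adjusted p = 1e-04) and CXCL8 from 8347 ± 80.6 to 5918 ± 293.6 CPM, while NLRP3 stood at 43.1 CPM in both groups (adjusted p = 1). NINJ1 was at 70.9 ± 10.0 and 44.1 ± 8.95 CPM (adjusted p = 0.0189), a call lost without SK56 replicate 1 (adjusted p = 0.0805), LPS and nigericin with SK56 replicate 1 (0.0783) or replicate 3 (0.0755). RASGEF1B, an exchange factor of small GTPases, fell from 173.9 ± 5.40 to 43.3 ± 0.73 CPM (log2 -2.01, SE 0.053, adjusted p = 1.57e-09), and EOMES, a T-box transcription factor, from 13.66 ± 0.81 to 2.74 ± 0.44 CPM. The pyroptosis list had 1 of 18 genes higher and 3 lower (1 and 3 adjusted over the list alone, camera adjusted p = 0.852, fry adjusted p = 0.285). In all, 934 genes were higher and 1038 lower, of which 264 and 115 by more than 2-fold, against 949 and 936 at a mean of at least 5 CPM. The median, mean and test differed in sign for the NF-kB feedback, pyroptosis, monoblast, glycolysis and LXR lists, none of which passed.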

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

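The tests of low-expressed protein-coding genes behind expressed genes were chosen after the result was seen. For the other tests of this part the limits were set out beforehand. The list and gene values given next were picked out because the test of the difference between both SK56 effects, at rest and under LPS and nigericin, passed its threshold. The patterns by gene structure and position at the end of this part were themselves noticed in these data, in other comparisons, and were not predicted. The test of the difference passed for 1406 genes with a higher and 1546 with a lower SK56 effect under the stimulus. Among lists whose call held with an estimated correlation, the median log2 difference was -1.79 for histones, -1.22 for immediate early genes, -1.14 for metallothioneins, -0.56 for the integrated stress response and -0.44 for ribosomal proteins. It was -0.34 for heat shock genes, -0.33 for LXR targets, -0.32 for the unfolded protein response, -0.28 for cholesterol synthesis and -0.25 for NF-kB feedback regulators. The other list calls were lost with an estimated correlation. Their median was -0.56 for mitochondrially encoded mRNAs (adjusted p = 0.0778 with an estimated correlation), -0.38 for NF-kB inflammatory cytokines (adjusted p = 0.0639), -0.26 for nuclear-encoded oxidative phosphorylation (adjusted p = 0.104) and -0.24 for lysosome and autophagy genes (adjusted p = 0.0891). It was -0.24 for glycolysis (adjusted p = 0.0778 with an estimated correlation), -0.23 for NRF2 targets (adjusted p = 0.0829), -0.05 for p53 targets (adjusted p = 0.0778) and 0.3 for toll-like receptors and adaptors (adjusted p = 0.152). The p53 and toll-like receptor calls were also lost with the replicate block (adjusted p = 0.0524 and 0.0686).

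Among single genes, the SK56 effect was higher under the stimulus for DLX3 by 3.656, CCDC71 by 2.791, HSPA6 by 1.395 and CCL2 by 0.524 on the log2 scale. For BIVM-ERCC5 (5.995), ZNF619 (2.341) and PDXP (2.298) overlapping genes make the reads uncertain, ZNF619 and PDXP also start 8526 bp after RPL14 and 2606 bp after SH3BP1 on the same strand, and for ZNF324B (3.046) no group mean was above 6.24 CPM. The log2 difference was -4.203 for PROK2 (chromosome 3, 71771655 to 71785206), -4.056 for TMEM160, -3.754 for TSC22D3, -3.389 for BOLA1 and -2.977 for C11orf96. TICAM2 had -3.661, which moved to -2.315 without SK56 replicate 1, and overlaps TMED7-TICAM2. The difference was -2.443 for EGR1, -2.21 for DUSP1, -1.801 for MT2A, -0.797 for MT-CO1, -0.785 for CXCL8, -0.454 for HSP90AB1, -0.296 for NLRP3 and -0.235 for IL1B.

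The PDXP call was lost without vehicle replicates 1, 2 or 3 (adjusted p = 0.0579, 0.0604 and 0.0632), LPS and nigericin replicates 1 or 2 (0.0821 and 0.0801), and LPS and nigericin with SK56 replicates 1 or 3 (0.0662 and 0.0708). With all libraries it was lost for PDXP with the replicate block (adjusted p = 0.0673) and with no low-count filter (0.052). The NLRP3 call was lost without 10 of the 12 libraries, at adjusted p from 0.061 to 0.121, and stayed without vehicle replicate 2 and without LPS and nigericin replicate 2. It was also lost with all libraries under other settings, at adjusted p from 0.0523 with DESeq2 size factors to 0.112 with no low-count filter.

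For the interaction, 1 of 60 splits of the 12 libraries, the real one, called as many as 2952 genes, and the highest other split called 1049. The other splits mix libraries of groups that differ, which widens the spread and lowers their counts, so this comparison does not by itself exclude chance. The other comparisons allow 10 splits each, too few for a share under 0.05. Their other splits also mix libraries of groups that differ, which lowers their counts, so the values given next do not exclude chance either. SK56 in resting cells called 4526 genes against 3 in the highest other split, LPS and nigericin without SK56 called 4868 against 2, SK56 under LPS and nigericin called 4634 against 2, and LPS and nigericin with SK56 called 1972 against 5. In each, 1 split reached the real count.

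Low-expressed protein-coding genes just behind expressed genes were higher after SK56 in resting cells. The 489 such genes within 20 kb after an expressed gene on its strand had a median of 0.4, against 0.04 for 217 genes within 20 kb before one, a difference of 0.368 that 0 of 2000 permutations reached (smallest p they can give 5e-04). After subtracting the neighbour's own change the difference was 0.419, which argues against a rise of the upstream gene, and olfactory receptor genes gained 0.34% of the reads per kb that the genes called higher gained, which argues against genomic DNA. Transcription running past the end of the upstream gene may account for the pattern, as a hypothesis found on these data, and PYGM (4632 bp after SF1) and CSPG5 (4477 bp after SMARCC1) lie in such places. A change of these genes' own promoters stays open, since reads between genes were not analysed here.

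Single-exon protein-coding genes had a median of -0.13 after SK56 in resting cells, with 67 of 231 called lower (29%) and 40 higher, against 13.5% lower and 1812 higher among 11891 spliced genes. Their median differed by -0.135 from that of spliced genes matched on length and expression, which argues against shorter transcripts, and olfactory receptor genes held 0.04% of the reads per kb lost, which argues against genomic DNA in the vehicle libraries. Fewer newly made short-lived mRNAs may account for part of it. Spliced zinc finger genes, the only class tried as short-lived, lay -0.346 from matched spliced genes. Immediate early genes, which were not tried as such a class, rose in the same comparison (median 1.07). After LPS and nigericin alone the medians were -0.33 for zinc finger and 0.04 for single-exon genes, so both classes moved apart. They did so too for SK56 under the stimulus, at 0.08 and -0.21. For LPS and nigericin with SK56 the medians were 0.12 and 0.07. A direct measure of mRNA lifetime was not analysed here.

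Noncoding genes within 10 kb behind expressed genes stood above other noncoding neighbours after LPS and nigericin, by 0.2 in medians (0.02 for 238 and -0.18 for 345 genes), which lies at the limit set for transcription running past the upstream gene. Of the first set 24 were called higher and 19 lower, and of the other set 31 and 64, so the difference comes almost wholly from lower values in the other set and not from a rise behind expressed genes. Olfactory receptor genes gained 0.06% of the reads per kb, which argues against genomic DNA. After subtracting the neighbour's own change the difference was 0.199, so that change accounted for almost none of it. The value lay just under the limit set for setting aside a rise of the upstream gene, so by that rule the question stayed unsettled. The same difference was 0.62 for SK56 in resting cells.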

How the results depend on the processing

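The tests with robust moderation, without MHC genes and without single-exon coding genes were chosen only after the data were seen. Where a named gene passed in the main or the alternative run, its fold change kept its sign, and no correlation changed sign. Named genes that passed in neither were not checked for sign. The balance of higher against lower calls, however, turned in 3 comparisons. At a mean of at least 5 CPM it was 1802 higher and 2036 lower for SK56 in resting cells, 1681 and 1381 for the interaction, and 949 and 936 for LPS and nigericin with SK56. It also turned without MHC genes (2209 and 2288, 1520 and 1445, 993 and 969). For SK56 in resting cells it turned as well with no low-count filter (1863 and 1903), without single-exon coding genes (2163 and 2223) and with only the 6 libraries compared (1986 and 2020). Leaving out any vehicle library or SK56 replicate 1 or 3 gave 1784 to 1872 higher and 1881 to 1906 lower. The interaction turned to 1238 to 1379 higher and 1204 to 1322 lower without any vehicle library, SK56 replicate 1, LPS and nigericin replicate 2 or 3, or LPS and nigericin with SK56 replicate 1 or 2. The stimulus effect with SK56 turned to 744 to 849 higher and 732 to 766 lower without SK56 replicate 1 or 3 or LPS and nigericin with SK56 replicate 1. These balances carry no direction. Of 1722 values of named genes with a library left out, 1674 stayed on their side of the threshold, 43 were lost and 5 gained, and under the other settings 2534 of 2572 stayed, 28 were lost and 10 gained. At a threshold of 0.01, fewer genes passed by construction. The counts of higher and lower genes were then 1426 and 1216 for SK56 in resting cells, 1520 and 1650 for LPS and nigericin without SK56, 1510 and 1315 for SK56 under the stimulus, 741 and 838 for the interaction, and 489 and 537 for LPS and nigericin with SK56. With only the 6 libraries compared in the fit, the last comparison had 683 lower genes, from fewer samples.

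Across genes, r between the stimulus effect and the SK56 effect under it was -0.419 with no low-count filter, -0.399 at a mean of at least 5 CPM and -0.401 with that minimum in the relation alone. For the stimulus effects without and with SK56 these values were 0.092, 0.467 and 0.47, and for both SK56 effects 0.204, 0.339 and 0.338. The cause was not tested. Leaving out each library gave -0.4 to -0.259, 0.323 to 0.38 and 0.428 to 0.5. Leave-one-out counts of higher and lower genes were 1784 to 2000 and 1732 to 1906 for SK56 in resting cells, 1916 to 2002 and 2159 to 2296 for LPS and nigericin, 2017 to 2146 and 1738 to 1932 for SK56 under the stimulus, 1205 to 1379 and 1204 to 1380 for the interaction, and 668 to 849 and 732 to 774 for LPS and nigericin with SK56.

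With an estimated correlation, 2 lists passed for SK56 in resting cells and 10 for the interaction, against 6 and 18. With fry, which does not compare a list with other genes, 19 passed for SK56 in resting cells, 28 for SK56 under the stimulus and 20 for LPS and nigericin with SK56. For LPS and nigericin without SK56 fry passed 28 lists, and for the interaction 27. Among the latter was the pyroptosis list, as lower (fry adjusted p = 0.0102).

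The replicate numbers did not pair the libraries. Deviations of same-numbered libraries had r from -0.04 to 0.065 over 18 pairs, and 0 of 12 libraries matched its own number in all other groups. With the replicate number as a block, 4224, 4605, 4337, 2710 and 1715 genes passed in the 5 comparisons, against 4526, 4868, 4634, 2952 and 1972, and r between the stimulus effects was 0.354. Under the block the interaction lost the p53 and toll-like receptor lists (adjusted p = 0.0524 and 0.0686) and no other list call was lost.

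Depth limits low genes. IL6, IL18, CASP5 and IL10 had 140, 185, 9 and 63 counts over all libraries, so small differences in them were not detectable at this depth.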

Other observations

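The tests of low-expressed coding genes by their place behind an expressed gene were chosen only after the result was seen, and the genes described here were picked from those the naming rule took after their values were seen. PLK3, a p53-responsive kinase, stood at 147 ± 2.14 CPM in vehicle, 73.4 ± 9.28 with SK56, 352.9 ± 10.9 under LPS and nigericin and 89.8 ± 1.88 with both, so that it fell with SK56 in stimulated cells (log2 -1.97, SE 0.074, adjusted p = 2.32e-08). IRF7, a regulator of interferon genes, went from 73.5 ± 2.15 to 39.6 ± 1.54 CPM in the same comparison (log2 -0.89, SE 0.051, adjusted p = 5.05e-07), although the list of interferon-stimulated genes did not pass there (camera adjusted p = 0.146). CDKN1A, the cell cycle inhibitor p21, rose under the stimulus from 968.2 ± 190.6 to 2887 ± 51.9 CPM (log2 1.58, SE 0.141, adjusted p = 9.98e-06) and fell with SK56 in stimulated cells to 1531 ± 42.1 CPM (log2 -0.92, SE 0.139, adjusted p = 0.000609).

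MCL1, an antiapoptotic BCL2 family member, rose with SK56 in resting cells from 1553 ± 40.2 to 2177 ± 20.98 CPM (log2 0.49, SE 0.028, adjusted p = 7.82e-07) and with LPS and nigericin to 4109 ± 132.5 CPM (log2 1.4, SE 0.028, adjusted p = 5.41e-11). GCLC, the rate-limiting enzyme of glutathione synthesis, was lower with SK56 both at rest (292.2 ± 11.9 and 191.7 ± 2.11 CPM, adjusted p = 8.76e-06) and under the stimulus (272.1 ± 17.5 and 185 ± 3.39 CPM, adjusted p = 1.33e-05). KRT4, a keratin gene that starts 7292 bp after KRT79 on the same strand, rose with SK56 in resting cells from 0.8 ± 0.066 to 5.23 ± 0.31 CPM (log2 2.7, SE 0.187, adjusted p = 3.15e-06) and was at 1.68 ± 0.41 CPM with SK56 and the stimulus.

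Within 20 kb behind an expressed gene lay 52.1% of the 219 low-expressed coding genes that SK56 raised over 2-fold in resting cells, against 14.2% of the others (Fisher's exact test, two-sided, p = 1.6e-35), and 53.5% of 172 under the stimulus against 14.8% (p = 1.4e-29). Genes are not independent replicates in these tests. Counts jumping from under 0.2 to over 5 CPM between libraries of a group were seen for 21 genes in vehicle, 15 in SK56, 15 in LPS and nigericin and 22 in LPS and nigericin with SK56.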
